A study of Mus musculus with 4 samples.

How the data were processed

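Gene expression was measured in the hearts of Balb/c mice after kidney surgery that left chronic kidney disease (CKD) and after a sham operation, on 2 arrays per group. Per the labels' protocols, total RNA was isolated with Trizol, biotin-labelled cDNA was made from 250 ng, and the samples were hybridised to Affymetrix Clariom S Mouse arrays, which carry short probes summarised into 1 value per transcript cluster (here called a probe set). The deposited values are log2 expression levels that were summarised and normalised with RMA, per the submitters' processing notes; the RMA software, its version and any filter are not given in the sources used here. RMA corrects the background, sets the arrays to a common distribution and summarises each probe set on the log2 scale, so that differences between arrays are log2 ratios, and it compresses ratios of probe sets near the background. No raw scans were used here, so background and normalisation could be varied only from the log2 values onward.

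The table held 22206 probe sets on 4 arrays. The platform's annotation paired 19572 of them with 1 gene symbol and 0 with several, and the other 2634 were unnamed here. All 19572 gene identifiers were found in the mouse reference gene table, and 0 symbols needed an update. Where a gene had several probe sets, the one with the highest mean over the 4 arrays was kept, which set aside 67 probe sets and left 19505 genes. No filter on low signal was applied. The array medians over all probe sets lay between 4.45 and 4.50 on the log2 scale. For arrays there is no read depth; their number, 2 per group with 2 residual degrees of freedom, limits the precision. The labels number the arrays 1 and 2 within each group and do not say whether they came from separate animals, and the design text speaks of hybridisation in duplicate. The p-values of single genes therefore measure only the spread between these arrays, which may be technical.

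CKD was compared with sham in a linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with the Benjamini-Hochberg adjustment over all genes and an adjusted p under 0.05 as the threshold. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with the adjustment over the 21 pathway lists and over the 20 marker lists separately. Camera with the estimated correlation and fry were run beside it. At the preset correlation, camera sets the genes of a list against the other genes as nearly independent units. Its p-values therefore treat genes, rather than arrays, as the replicates. The lists held 790 different genes, of which 719 were measured; the list of sex-linked genes was kept apart from the tests. The pathway lists covered hypertrophy, contraction, calcium handling, extracellular matrix, inflammation, interferon, antigen presentation, fuel use, respiration, oxidative stress, hormones, phosphate and FGF23, the clock, the cell cycle, hypoxia, immediate early genes, protein folding and protein degradation. The marker lists covered the cell types of the heart, blood and immune cells, adipocytes, skeletal muscle, nerve, cartilage, and thymus with lung. Groups, test, lists, the rule for naming genes and all alternatives but the crossed pairing and the estimated correlation without CKD replicate 1 were fixed before the data were examined.

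Genes were named by this rule. The 12 genes with the largest rise and the 12 with the largest fall past the threshold, with both CKD arrays on one side of both sham arrays, were to be named. Where fewer passed, each direction was filled to 12 by the smallest unadjusted p among genes with the same separation and a fold of at least 1.5, and these are reported as values that did not pass. Predicted genes, receptor clusters and immunoglobulin segments were counted but not named. Up to 4 members of a list were named by size, and 19 genes of cardiac load, fibrosis, phosphate handling and fuel use were to be named whatever their value. Of these, 1 is not reported here. A few further genes, among them Ccr9 and Themis, were chosen after their values were seen.

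The scripts were tested on simulated data with the spread of these arrays, in which 200 of the 19505 genes were moved by known amounts. The test recovered 0% of 50 genes moved by 1 on the log2 scale, 34% of 50 moved by 2, 92% of 50 moved by 4 and 94% of 50 moved by 6, with 4 false calls. The simulated spread was equal in both groups and independent between genes, whereas in the data 12821 genes had a larger SD in CKD than in sham. The shares recovered therefore need not hold for the data. Alternatives covered repeated quantile normalisation, a common median, filters on dim genes, a variance trend with and without robust priors, the mean over a gene's probe sets, all probe sets, the replicate number as a block, each array left out in turn, other thresholds, an unmoderated test, and camera on ranks or without shared genes. Figures were drawn with matplotlib 3.10.9. Python 3.11.15 was used for the figures. The array's genome build is not given in the sources used here, so no coordinates are reported.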

Results

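Hearts of mice with CKD were compared with hearts of sham-operated mice to find genes whose expression differed between them. CKD had been produced by electrocoagulation of the cortex of the right kidney followed by removal of the left kidney, and sham mice had their abdomen opened without kidney surgery. Each group was measured on 2 arrays, and all values are RMA expression levels on the log2 scale. The sham arrays resembled each other closely (Pearson r = 0.989 across 19505 genes, which are not independent replicates), and CKD replicate 2 correlated with them at 0.983 and 0.986. CKD replicate 1 stood apart, with correlations of 0.932 and 0.946 with the sham arrays and 0.948 with the other CKD array. It held 867 genes at least 2-fold higher and 366 at least 2-fold lower than on each of the other 3 arrays, against 37 and 2 for CKD replicate 2.

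Expression of the Y-linked gene Eif2s3y, which encodes a subunit of a translation initiation factor, was 8.08 ± 0.08 in CKD hearts and 1.43 ± 0.20 in sham hearts (SD, n = 2). This difference of 6.64 on the log2 scale (SE 0.21) corresponded to 99.9-fold and passed the threshold in limma (adjusted p = 0.00616). Gdpd3, an enzyme that cleaves lysophospholipids, went the other way, from 8.76 ± 0.09 in sham to 2.71 ± 0.18 in CKD hearts (SD, n = 2), a log2 difference of -6.04 (SE 0.21, limma adjusted p = 0.00616) or 66.0-fold. These were the only genes past the threshold in limma, 1 higher and 1 lower in CKD. The sham levels of Eif2s3y lay close to the lowest values on those arrays (0.89 and 0.92), and Gdpd3 measured 2.59 and 2.84 on the CKD arrays, whose lower quartiles were 2.75 and 2.73, so both folds depend on the background.

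2 further Y-linked genes, both of histone demethylase families, separated the groups in the same direction without passing. Uty measured 2.04 and 1.29 on the sham arrays and 7.26 and 6.99 on the CKD arrays, a difference of 5.46 (SE 0.31, limma adjusted p = 0.0536). Kdm5d measured 1.84 and 2.03 in sham and 5.65 and 4.59 in CKD hearts, a difference of 3.19 (SE 0.38, limma adjusted p = 0.456). All 3 measured genes of the Y-linked list were thus near the background on both sham arrays, and their mean was 7.01 and 6.53 on the CKD arrays. Xist and Ddx3y are not analysed here. The Y-linked values argue against hearts of the same sex in both groups. The labels do not give sex, and its effects on other genes cannot be told apart from those of CKD.

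Other genes with large, non-overlapping differences did not pass the threshold over all genes and are given as values. Higher in CKD hearts were H2-Eb1, a chain of an MHC class II molecule (3.60, SE 0.36), Hp, which encodes the haemoglobin-binding protein haptoglobin (3.51, SE 0.39), and Pttg1, the securin of mitosis (3.31, SE 0.40). The interferon-inducible Ifi200 family members Ifi207 and Mndal differed by 2.99 (SE 0.31) and 2.59 (SE 0.22). Trim30d (2.27), Cyfip2 (2.26), a part of an actin-regulating complex, Fam205a2 (1.78) and Lipo3 (1.61) completed the higher genes. Trim30d lay in the background on the sham arrays (1.88 and 1.91), and Hp (2.95 and 2.62) and Fam205a2 (2.80 and 3.01) lay near it. The differences of Trim30d, Hp and Fam205a2 are therefore only approximate. Lower in CKD hearts was Casq1, a calcium-binding protein of the sarcoplasmic reticulum, at 8.47 and 8.28 in sham and 4.31 and 5.31 in CKD hearts, a log2 difference of -3.57 (SE 0.37, limma adjusted p = 0.316). Sun3 (-3.19), the antiprotease gene Serpina1a (-2.48), the glycosyltransferase gene Gcnt1 (-2.42), the formin Fmn1 (-1.995), the mitochondrial ribosomal protein gene Mrpl20 (-1.97) and the oxygen-sensing hydroxylase gene Egln3 (-1.90) followed. Pianp (-1.82), Hddc3 (-1.54), the lipid flippase gene Atp10d (-1.34) and the collagen hydroxylase gene P4ha1 (-1.09) completed the lower genes, and the difference of Sun3, near the background on the CKD arrays (1.32 and 2.76), is likewise approximate. The limma adjusted p of these genes ranged up to 0.727 (Sun3 and P4ha1). As a ranking and not as calls, 182 genes had an unadjusted p under 0.01 and at least a 1.5-fold difference, 111 higher and 71 lower. At an unadjusted p under 0.05 there were 1069 genes, against 975 by chance. The groups did not overlap for 7969 genes, or 40.9%, against 33.3% by chance, and in 61 genes both CKD arrays lay at least 2-fold above both sham arrays, in 24 at least 2-fold below.

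**Figure D1:**
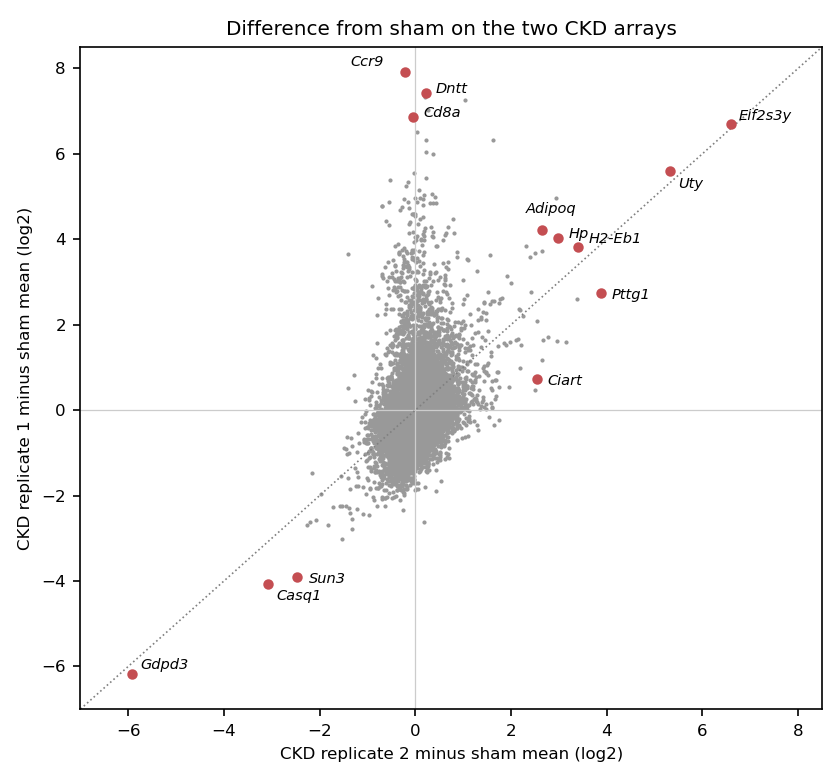
Each point is a gene, placed by its log2 difference from the mean of the 2 sham arrays on CKD replicate 2 (horizontal axis) and on CKD replicate 1 (vertical axis); the dotted line marks equal differences, and red points are named. Eif2s3y and Gdpd3 lie near the line at 6.59 and 6.70 and at -5.92 and -6.17, whereas Dntt, Ccr9 and Cd8a lie near 0 on CKD replicate 2 and at 7.43 (Dntt), 7.91 (Ccr9) and 6.87 (Cd8a) on CKD replicate 1.

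CKD replicate 1 alone carried transcripts of developing T cells. Dntt, the terminal transferase of V(D)J recombination, measured 9.17 on this array and 1.84, 1.65 and 1.96 on sham replicate 1, sham replicate 2 and CKD replicate 2. The T cell co-receptor genes Cd8a (10.44) and Cd8b1 (10.27) exceeded the highest of the other 3 arrays, which were 4.06 and 4.04. In the T cell and natural killer cell list the median difference from the sham mean was 4.33 on CKD replicate 1 and -0.29 on CKD replicate 2. As a set its 11 measured members were higher in CKD (camera adjusted p = 0.00678), although 0 passed adjusted over the list alone; the adjusted p was 0.790 with an estimated correlation. Without CKD replicate 1 the direction turned (camera adjusted p = 0.550). The thymus and lung list, which also holds Dntt, did not pass (camera adjusted p = 0.185), and in it Cd1d1 differed by 0.88, Ptcra by 0.43 and the lung gene Scgb1a1 by -0.17.

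Cell cycle genes followed the same array. Of 29 measured members all had a higher mean in CKD, among them Bub1b (2.64, SE 1.40), the proliferation marker Mki67 (2.58, SE 1.51), the mitotic kinesin Kif11 (2.45, SE 1.53) and Bub1 (2.28, SE 1.47), and 0 passed adjusted over the list alone; Bub1b, Kif11 and Bub1 were near the background on the other 3 arrays (1.48 to 2.79). As a set they were higher in CKD (camera adjusted p = 1.6e-09; adjusted p = 0.899 with an estimated correlation). The median difference from sham was 3.45 on CKD replicate 1, where the T cell list stood at 4.33, and 0.03 on CKD replicate 2, and the call ended without CKD replicate 1 (camera adjusted p = 0.453).

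Lists of the heart's own machinery were lower in CKD as sets. In the oxidative phosphorylation list, 30 of 51 members were lower on both CKD arrays than on both sham arrays and 0 passed adjusted over the list alone (camera adjusted p = 2.1e-06; adjusted p = 0.899 with an estimated correlation). Its members with the largest differences were Ndufa8 (-0.98), Cox8b (-0.75), Cox6a2 (-0.74) and Ndufs7 (-0.73). In the adult contractile apparatus 11 of 23 members were lower on both CKD arrays and 0 passed adjusted over the list alone (camera adjusted p = 0.000436; 0.899 with an estimated correlation), with Cryab (-1.04), Pdlim5 (-0.99), Myot (-0.93) and Ldb3 (-0.91) in front. Among 29 calcium handling and ion channel genes 1, Casq1, passed adjusted over the list alone (camera adjusted p = 0.00110; 0.899 with an estimated correlation), and Cacna1c (-1.02), Kcnip2 (-1.01) and Kcnv2 (-0.90) did not. The lower values sat on CKD replicate 1, where the median differences were -0.71 for oxidative phosphorylation, -0.88 for the contractile apparatus and -0.85 for calcium handling, beside 4.33 for the T cell list. On CKD replicate 2 they were -0.07, -0.07 and 0.10. Casq1 did not follow its list, at -4.07 and -3.07 from the sham mean on CKD replicates 1 and 2. Without CKD replicate 1 the calls ended (camera adjusted p = 0.510, 0.622 and 0.622), and the calcium handling list turned upward.

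Hypertrophy and fetal genes, which heart muscle re-expresses under load, were lower as a set, with 12 of 19 members lower on both CKD arrays and 0 past adjusted over the list alone (camera adjusted p = 0.000365; adjusted p = 0.899 with an estimated correlation). The median difference was -1.07 on CKD replicate 1, where the T cell list stood at 4.33, and -0.27 on CKD replicate 2, and the call ended without CKD replicate 1 (camera adjusted p = 0.0595). Myh7, the slow myosin heavy chain, measured 11.16 and 10.94 in sham and 9.19 and 10.40 in CKD hearts, a difference of -1.26 (SE 0.43). Nmrk2 (-1.22, SE 0.24), the skeletal actin gene Acta1 (-1.12, SE 0.37) and Tnfrsf12a (-1.08, SE 0.53) differed by similar amounts. The natriuretic peptide genes stayed within the spread, Nppa at 0.17 (SE 0.24) and Nppb at -0.77 (SE 0.48). So did Myh6 (-0.11, SE 0.25), the stress-responsive Ankrd1 (-0.01, SE 0.27) and the calcium pump gene Atp2a2 (-0.06, SE 0.22), and none of these genes passed in limma.

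**Figure D2:**
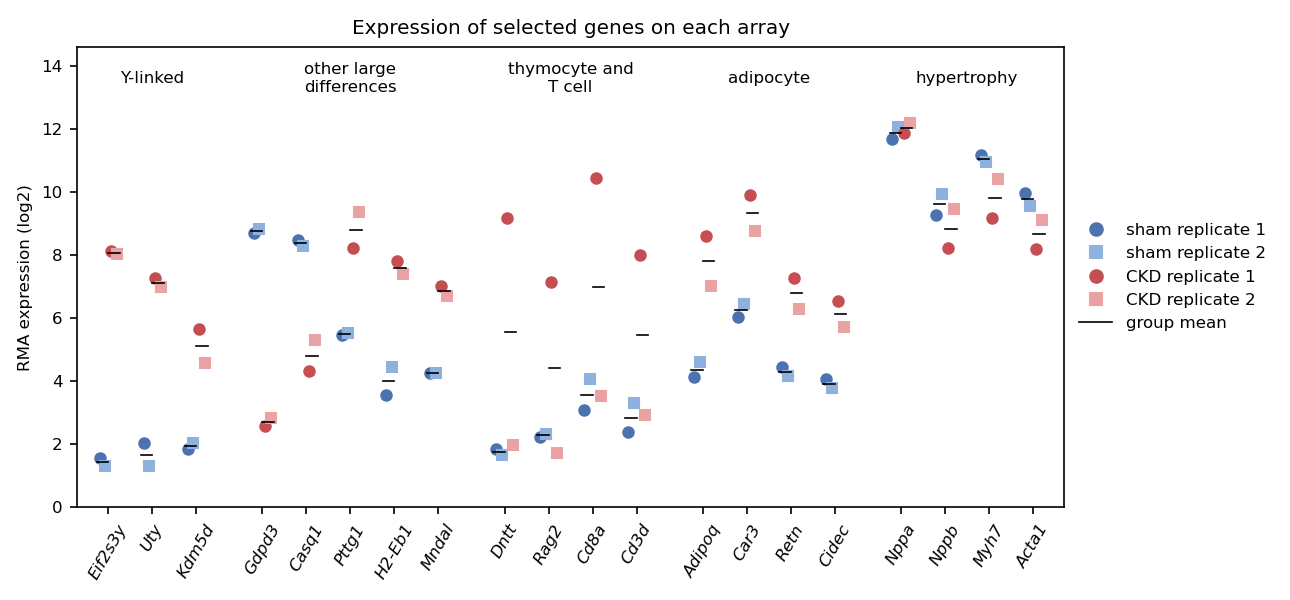
RMA expression (log2, vertical axis) of selected genes on each of the 4 arrays, with sham in blue, CKD in red, circles for replicate 1, squares for replicate 2 and short lines for group means. Y-linked genes and Gdpd3 separate the groups, thymocyte and T cell genes are high on CKD replicate 1 alone (Dntt at 9.17), and the 4 adipocyte genes shown are higher on both CKD arrays (Adipoq at 8.59 and 7.02).

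White adipocyte genes were higher in CKD as a set. Of 8 measured members 6 were higher on both CKD arrays than on both sham arrays, 6 rose adjusted over the list alone, and 0 passed over all genes. Adipoq, which encodes the hormone adiponectin, measured 4.12 and 4.61 in sham and 8.59 and 7.02 in CKD hearts (3.44, SE 0.55). The carbonic anhydrase gene Car3 (3.09, SE 0.43), the resistin gene Retn (2.49, SE 0.37) and the lipid droplet gene Cidec (2.22, SE 0.32) followed. The list as a whole passed (camera adjusted p = 1.1e-08; adjusted p = 0.790 with an estimated correlation), with median differences of 2.60 on CKD replicate 1 and 1.42 on CKD replicate 2, and it stayed past the threshold without CKD replicate 1 (camera adjusted p = 3.9e-13; 0.998 with an estimated correlation). In the brown adipocyte list Ucp1, the uncoupling protein of brown fat, differed by 2.60 (SE 0.67), Elovl6 by 1.54 and Ppargc1a by -1.24, and the list did not pass (camera adjusted p = 0.603); Ucp1 lay in the background on the sham arrays (1.997 and 1.87), so its difference is approximate.

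Other marker lists called by camera lost the call with an estimated correlation (adjusted p = 0.790 for each). B cell and plasma cell genes were higher, with 5 of 7 members higher on both CKD arrays and 0 past adjusted over the list alone (camera adjusted p = 0.00678); Jchain, the joining chain of secreted antibodies, measured 3.27 and 6.18 in sham and 9.70 and 7.66 in CKD hearts. In the mast cell list 1 of 7 members, Cpa3 (2.12, SE 0.30; in the background at 2.39 and 2.46 in sham), rose adjusted over the list alone (camera adjusted p = 0.0458). Macrophage and monocyte genes were higher with 0 of 13 members past adjusted over the list alone (camera adjusted p = 0.0458), and the haptoglobin receptor gene Cd163 differed by 0.91 (SE 0.21) and the chemokine receptor gene Ccr2 by 0.94 (SE 0.38). Endothelial and fibroblast lists were lower, with 0 of 11 and 0 of 10 members past adjusted over the list alone (camera adjusted p = 0.0458 for each). Ly6c1 (-0.73) and Emcn (-0.61) led the endothelial genes, and Tcf21 (-0.90) and Medag (-0.85) the fibroblast genes. The endothelial and fibroblast medians were -0.78 and -0.80 on CKD replicate 1, beside 4.33 for the T cell list, and -0.02 and -0.12 on CKD replicate 2. Without CKD replicate 1 none of these 5 calls remained, at camera adjusted p of 0.110 (B cell), 0.0872 (mast cell and macrophage), 0.964 (endothelial) and 0.838 (fibroblast). The medians on CKD replicates 1 and 2 were 1.43 and 0.20 for the B cell list, 0.54 and 0.22 for the mast cell list and 0.15 and 0.22 for the macrophage list, so the last was no smaller on CKD replicate 2.

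The immediate early list and the protein folding list had similar medians below sham on both CKD arrays. The immediate early list had median differences of -0.29 and -0.25 on CKD replicates 1 and 2, with 12 of 25 members lower on both CKD arrays and 0 past adjusted over the list alone (camera adjusted p = 0.00575; adjusted p = 0.899 with an estimated correlation). Its largest differences were Myc (0.79), Klf2 (-0.79), Fos (-0.79) and Dusp1 (-0.76). Of these, only Fos was alike on CKD replicates 1 and 2, at -0.84 and -0.735 from the sham mean. Myc was at 1.575 and 0.01, Klf2 at -1.20 and -0.38, and Dusp1 at -1.36 and -0.15. The protein folding and endoplasmic reticulum stress list had medians of -0.27 and -0.25, with 12 of 26 members lower on both and 0 past adjusted over the list alone (camera adjusted p = 0.00575; 0.899 with an estimated correlation), led by the heat shock genes Hspb1 (-1.71, SE 0.51) and Hsph1 (-0.95, SE 0.19). Both stayed past the threshold without CKD replicate 1 (camera adjusted p = 0.00310 each; 0.846 each with an estimated correlation), without CKD replicate 2 they were at 0.0964 and 0.0831, and without sham replicate 2 the immediate early list was at 0.170 and the protein folding list at 0.0113. The protein folding list was the only pathway list past the threshold in fry (adjusted p = 0.0478).

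The hypoxia list and the glycolysis list were lower as sets and shared a member that rose. In the hypoxia list, 21 genes, Egln3 (-1.90) and P4ha1 (-1.09) fell and Pfkfb3 (1.54, SE 0.21), the kinase that makes an activator of glycolysis, rose adjusted over the list alone (camera adjusted p = 0.0151; 0.899 with an estimated correlation), and P4ha2 measured -1.35. In the glucose uptake and glycolysis list, 28 genes, 1 member, Pfkfb3, rose adjusted over the list alone (camera adjusted p = 0.00290; 0.899 with an estimated correlation), and Slc2a12 (-1.04), Pdk2 (-0.99) and Pgam2 (-0.96) did not pass. Their medians were -0.53 and -0.63 on CKD replicate 1, beside 4.33 for the T cell list, and -0.17 and -0.08 on CKD replicate 2, and both calls ended without CKD replicate 1 (camera adjusted p = 0.0841 and 0.622).

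**Figure D3:**
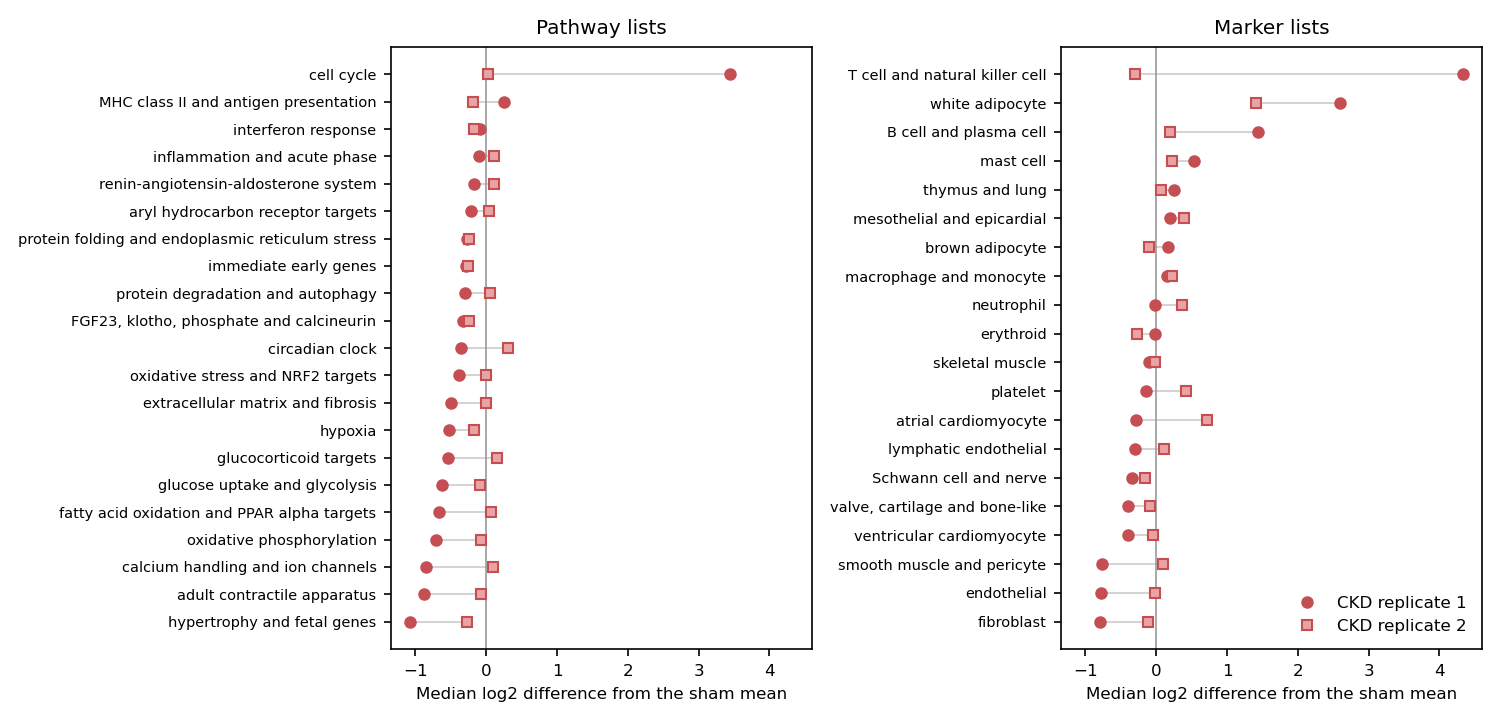
Median log2 difference from the sham mean (horizontal axis) of the 21 pathway lists (left) and the 20 marker lists (right), as circles for CKD replicate 1 and squares for CKD replicate 2. The T cell list lies at 4.33 and -0.29 and the cell cycle list at 3.45 and 0.03, whereas the white adipocyte list lies at 2.60 and 1.42.

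The remaining 12 pathway lists did not pass in camera. Extracellular matrix and fibrosis genes had 0 of 44 members past adjusted over the list alone (camera adjusted p = 0.0944). The protease gene Mmp3 differed by 2.37 (SE 0.55), which is approximate because it was near the background on the sham arrays (2.996 and 2.44). Tnc differed by 1.27 (SE 0.97), at 2.79 and -0.24 from the sham mean on CKD replicates 1 and 2. Fbln1 differed by -1.08, at -1.69 and -0.47. Col1a1 (-0.50, SE 0.26) and Ccn2 (-0.57, SE 0.34) were lower on both CKD arrays than on both sham arrays without passing in limma, and in the collagen gene Col3a1 (-0.45, SE 0.35), Postn (0.00, SE 0.35) and Tgfb1 (0.06, SE 0.30) the groups overlapped. In the fatty acid oxidation list (camera adjusted p = 0.0655) Ppargc1a differed by -1.24, Angptl4 by 0.90 and the pyruvate dehydrogenase kinase gene Pdk4 by -0.48 (SE 0.40). In the phosphate list (camera adjusted p = 0.111) Fgf23, the phosphate hormone of bone, was near the background at 2.79 ± 0.20 in sham and 2.42 ± 0.09 in CKD hearts (SD, n = 2), and its receptor genes Kl (0.09) and Fgfr4 (-0.39) were as dim. In the antigen presentation list (camera adjusted p = 0.176, and 0.00240 to 0.939 with 1 array left out) 1 of 11 members, H2-Eb1, rose adjusted over the list alone, followed in size by H2-DMb1 (1.18), Ctss (0.69) and H2-Ab1 (0.65); the list's median of -0.10 and mean of 0.41 differed in sign, and the test pointed upward. Inflammation (camera adjusted p = 0.516) held Cxcl13 (1.69) and Ccl11 (1.27), with Lcn2 at -0.17 (SE 0.57). The interferon list (camera adjusted p = 0.664) held Cxcl9 (1.37), Bst2 (1.03) and Igtp (-0.91). The camera adjusted p was 0.497 for the renin-angiotensin-aldosterone list, where Agtr1a differed by 0.18 (SE 0.42) and Hsd11b1 by 0.75, and 0.40 for protein degradation, where Ctsl differed by 0.85. It was 0.611 for oxidative stress, 0.878 for glucocorticoid targets, where Ptgds differed by -1.30 and Fkbp5 by 1.20, and 0.998 for aryl hydrocarbon receptor targets. Against the sham mean, Ptgds was at -2.335 on CKD replicate 1 and -0.265 on CKD replicate 2, and Fkbp5 at 2.25 and 0.15. For the circadian clock the camera adjusted p was 0.855, with a median of -0.06 against a mean of 0.11 and an upward test. Arntl differed by 1.77, at 3.23 and 0.315 from the sham mean on CKD replicates 1 and 2. Ciart differed by 1.64, at 0.73 and 2.55, so each rested mainly on a different array.

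Among the remaining marker lists, the camera adjusted p was 0.0937 for atrial cardiomyocytes, 0.105 for ventricular cardiomyocytes (0.0183 to 0.964 with 1 array left out) and for neutrophils, and 0.109 for smooth muscle and pericytes. It was 0.185 for mesothelial, 0.219 for Schwann cell, 0.258 for valve and cartilage, 0.610 for platelet, 0.801 for erythroid, and 0.837 for lymphatic endothelial and skeletal muscle genes. The skeletal muscle list had a median of -0.01 and a mean of 0.01. Atrial genes had a median difference of -0.28 on CKD replicate 1 and 0.71 on CKD replicate 2, and Bmp10, an atrial growth factor, measured 5.08 and 9.02 in sham and 8.68 and 9.71 in CKD hearts. Ckm (-0.73) and Irx4 (-0.66) led the ventricular list, and S100a8 (0.83) and Ngp (0.75) the neutrophil list.

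The gene calls depended on single arrays. Without CKD replicate 1, 77 genes passed in limma, 64 higher and 13 lower, among them Eif2s3y and Gdpd3; without CKD replicate 2 there were 3346, and without sham replicate 1 or sham replicate 2 there were 0, with 206 and 302 genes at an unadjusted p under 0.05.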

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

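Written before their results were seen were the tests of thymic epithelial genes and of genes that escape X inactivation; the tests of mature T cells, another organ, dilution, exchanged samples, interferon, neighbouring genes in its final form, and other splits were chosen after the values they use had been seen.

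Outside the genes compared in the report, 5 probe sets without a gene name here were at least 4-fold higher on both CKD arrays than on both sham arrays, and 1 was at least 4-fold lower. The 5 higher ones are a signal above the level of the control arrays in probe sets that the comparison of named genes left out, and 1 unnamed probe set passed the threshold when all probe sets were fitted together.

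Thymocyte genes were high on CKD replicate 1 alone, with Themis at 10.70, Cd8a at 10.44, Cd8b1 at 10.27 and Ccr9 at 9.95, and heart lists were lower there. Mature T cells alone are argued against by Dntt, Rag2 and Ptcra, genes of immature thymocytes, whose median lay 5.06 above the mean of the other 3 arrays, and another organ in place of a heart is argued against by the ventricular cardiomyocyte list, whose median lay only -0.40 from sham. Dilution of heart RNA by another tissue would lower all heart cells alike, and the median of fibroblast, endothelial and smooth muscle genes differed from that of the contractile genes by 0.10 (bootstrap SE 0.17). The comparison left out the ventricular and atrial cardiomyocyte lists. On this array their medians were -0.40 and -0.28, against -0.885 for the contractile list, so not all heart lists were lowered alike. Thymus lying next to the heart may be the source, but the median of 7 thymic epithelial genes, which needed to exceed 0.5, was 0.47, with Psmb11, Epcam and Foxn1 at 2.97, 2.04 and 1.16 and Dll4, which sham hearts also express, at -0.99. Thymus tissue therefore stays open, as does an effect of CKD seen on 1 of the 2 CKD arrays, which was not tested.

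Eif2s3y, Uty and Kdm5d were high on both CKD arrays and near the background on both sham arrays. Whether samples were exchanged between the groups stays open, because the 0 arrays with a Y-linked mean out of line with their group only restate the pattern. If sham hearts came from females and CKD hearts from males, genes that escape X inactivation could be lower in CKD by more than 0.2 on both arrays, and their median was -0.056 on CKD replicate 1 and -0.46 on CKD replicate 2. The median passed that limit only on CKD replicate 2, so the escape genes do not decide whether sex differed. The mean of the 3 Y-linked genes was 1.815 and 1.54 on the sham arrays and 7.01 and 6.53 on the CKD arrays. These values argue against hearts of the same sex in both groups, although the labels do not give sex. A sex difference would go with the group, so for all other genes its effects cannot be told apart from those of CKD. Of the 3 splits of the arrays into 2 and 2, 1, the real one, gave 2 genes past the threshold and the highest other gave 0, and 3 splits are too few for a share under 0.05.

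In 85 genes both CKD arrays lay at least 2-fold from both sham arrays on the same side, among them Ifi204, Ifi207, Ifi208, Ifi211, Ifi213 and Mndal of the Ifi200 family. An interferon response stays open, because the interferon list had a median of -0.094 on CKD replicate 1 and -0.17 on CKD replicate 2 against the sham mean, but of 0.35 and 0.13 against sham replicate 1 and -0.26 and -0.65 against sham replicate 2, and the sham arrays themselves lay 0.82 apart over it. A different genetic background of the groups might place such genes close together, and 10 pairs with unlike symbols lay within 10 tested genes against a random median of 3 (permutation p = 0.00190, one-sided, 10000 draws). Of these pairs 6 joined members of one family, 5 of them Mndal with Ifi genes, and with pairs of one family left out, a change made after that result was seen, 4 pairs remained against 3 (permutation p = 0.365). Genetic background and CKD therefore cannot be told apart for these genes, because the design holds no further group from either source.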

How the results depend on the processing

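All alternatives were planned but the crossed pairing and the estimated correlation without CKD replicate 1. Eif2s3y and Gdpd3 kept their direction in every setting in which single genes were refitted, and passed there in all but the fits without a sham array; neither passed in the unmoderated test. Genes changed, higher and lower numbered 0, 0 and 0 in the unmoderated test, 4, 3 and 1 over all probe sets, and 2 higher after quantile normalisation, limma-trend with or without robust priors, and at adjusted p under 0.1. Leaving out an array in turn gave 0 to 3346 genes changed, 0 to 1736 higher and 0 to 1610 lower, 3 to 12 pathway lists and 3 to 11 marker lists; a lone array is assumed to vary like the other group, so the large spread between the CKD arrays enters when a sham array is left out. Camera with an estimated correlation called 0 pathway and 0 marker lists, as it did without CKD replicate 1 (0 and 0), and fry 1 and 0. Marker lists called numbered 2 with either filter on dim genes, 3 with limma-trend and 3 without genes in 2 or more lists. Direction turned for Ankrd1 after quantile normalisation (0.07), for skeletal muscle with the milder filter on dim genes (adjusted p = 0.846), without genes under the median (0.475) and in fry (0.918), for aryl hydrocarbon receptor targets without genes under the median (0.614) and on ranks (0.980), for brown adipocyte and Schwann cell lists without them (0.850 each), and for the clock in fry (0.943). The cause was not tested.

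Calls that passed as reported ended for the macrophage list after quantile normalisation (adjusted p = 0.0728) and for the endothelial and fibroblast lists with a common median (0.0529 each). With the milder filter on dim genes they ended for the hypoxia list (0.0514), the B cell, endothelial and fibroblast lists (0.0642 each), the macrophage list (0.0701) and the mast cell list (0.0522), and without genes under the median for the B cell (0.475), endothelial and fibroblast (0.0664 each) and macrophage (0.103) lists, while the mast cell list was too small to test. With limma-trend they ended for the endothelial, fibroblast, macrophage and mast cell lists (0.0535 each), on ranks for the mast cell list (0.0897), and without genes in 2 or more lists for the endothelial (0.0592), fibroblast (0.117), macrophage (0.0585) and mast cell (0.183) lists. Calls were gained for extracellular matrix (0.00168) and fatty acid oxidation (0.0415) without genes under the median, for fatty acid oxidation (0.0249) and atrial genes (0.0493) on ranks, and for Uty after quantile normalisation (0.0452) and with limma-trend (0.0368; 0.0190 with robust priors).

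Direction also turned when 1 array was left out, with log2 differences between -0.02 and 0.36 for Nppa, -0.36 and 0.15 for Myh6, -0.26 and 0.24 for Ankrd1, -0.21 and 0.10 for Atp2a2, -0.36 and 0.36 for Postn, -0.25 and 0.37 for Tgfb1, -0.24 and 0.42 for Kl, -0.42 and 0.78 for Agtr1a, -0.97 and 0.004 for Pdk4, and -1.02 and 0.68 for Lcn2. The camera adjusted p ranged from 0.622 to 0.743 for aryl hydrocarbon receptor targets, 1.7e-09 to 0.622 for calcium handling, 0.00310 to 0.522 for the clock, 0.000117 to 0.412 for extracellular matrix, 1.4e-05 to 0.939 for fatty acid oxidation, 0.0629 to 0.568 for glucocorticoid targets, 0.0210 to 0.860 for inflammation, 7.2e-08 to 0.649 for interferon, 0.146 to 0.757 for oxidative stress and 0.0549 to 0.682 for protein degradation. For markers it ranged from 5.0e-09 to 0.692 for atrial, 0.120 to 0.898 for erythroid, 0.5996 to 0.838 for lymphatic, 0.00858 to 0.924 for mesothelial, 0.000537 to 0.898 for platelet, 0.584 to 0.972 for skeletal muscle, 0.00330 to 0.899 for smooth muscle, 2.6e-12 to 0.550 for T cell and 0.00486 to 0.993 for valve lists. Without a turn in direction, calls also ended or were gained for immediate early genes, at 0.0964 without CKD replicate 2 and 0.170 without sham replicate 2, for antigen presentation, at 0.00240 without sham replicate 2 and 0.0443 without CKD replicate 2, for ventricular genes, at 0.0183 without CKD replicate 2 and 0.0441 without sham replicate 2, and for thymus and lung, at 0.0221 without CKD replicate 2. Endothelial and fibroblast lists were at 0.185 each without sham replicate 2, macrophage genes at 0.147 without CKD replicate 2 and 0.612 without sham replicate 1, and mast cell genes at 0.0614 and 0.0519 there; protein folding was at 0.0831 without CKD replicate 2, neutrophil genes passed without CKD replicate 1 (0.000388), and the report gives the other calls that ended without it.

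The arrays share only a replicate number: deviations of same-numbered arrays correlated at -0.229 over genes. With the replicate block 2 genes passed, 11 pathway and 9 marker lists were called, and the extracellular matrix (0.0309), fatty acid oxidation (0.0428), atrial (0.0197) and neutrophil (0.0243) lists passed in addition. With the numbers crossed, chosen after seeing the data, 6 genes passed, 4 higher and 2 lower. Signal over background limits genes such as Fgf23, whose values lie near the lower quartile of each array (2.73 to 2.77).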

Other observations

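Several genes differed between the 2 sham arrays; they were chosen after their values were seen, and no test of a common theme was run. The platelet chemokine gene Ppbp measured 5.13 on sham replicate 1 and 8.82 on sham replicate 2, and Pf4 measured 6.01 and 7.18. The interferon-induced genes Rsad2 (4.51 and 7.24), Irf7 (4.77 and 6.64) and Cxcl9 (4.14 and 6.25) differed the same way. The median of sham replicate 2 minus sham replicate 1 was 1.26 over the platelet list, 0.82 over the interferon list, 0.99 over the T cell list and 0.40 over the atrial list, but 0.07 over the neutrophil list, 0.08 over the B cell list and 0.07 over the mast cell list. Other lists also differed, among them antigen presentation (0.65), mesothelial (0.45), cell cycle (0.42), macrophage (0.30) and valve (-0.59) lists. The macrophage list had a median CKD difference of 0.25. Bmp10 showed the widest gap of all genes between the sham arrays, 5.08 against 9.02, and Chad, a cartilage matrix gene, measured 6.80 and 3.80.

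CKD replicate 2 set against the sham arrays alone gave 3 pathway and 3 marker lists, of which the white adipocyte, immediate early and protein folding lists were also called in the fit of all arrays. The others were not repeated on CKD replicate 1, where the medians were -0.28 (atrial), -0.01 (neutrophil) and -0.36 (clock). Atrial genes were higher (camera adjusted p = 5.0e-09; median 0.71), as were neutrophil genes (3.9e-04; median 0.37) and clock genes (0.00310; median 0.31), the last led by Ciart, a repressor of the clock, at 6.90 against 4.54 and 4.16 in sham. With an estimated correlation, which rests on 1 residual degree of freedom here, the adjusted p was 0.998 for the atrial and neutrophil lists and 0.846 for the clock, and in the fit of all arrays it was 0.790, 0.790 and 0.99. Genes past the threshold in limma on this array that were less raised on CKD replicate 1 included the growth factor gene Fgf1 (2.66 and 1.18 above the sham mean on CKD replicates 2 and 1), the matrix protease gene Mmp3 (3.15 and 1.58) and the complement gene C7 (1.75 and 0.54). These 3 genes were chosen after their values were seen. Mmp3 was near the background on the sham arrays (2.996 and 2.44), so its differences are approximate.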
